A study of Drosophila melanogaster with 4 samples.

How the data were processed

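Monomethylation of lysine 36 on histone H3 (H3K36me1) was mapped by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in nuclei of Drosophila melanogaster larvae of instar 3. The strain was Oregon-R, a standard laboratory wild type. Per the labels' protocols, tissue was homogenised and fixed with formaldehyde, the chromatin was sheared by sonication, and antibody was added for 15 hours. The series held 4 samples in 2 groups, with 2 H3K36me1 ChIP samples and 2 input samples, and the labels number the samples of each group as replicate 1 and replicate 2. Nothing in the labels says that the replicates came from separate cultures or collections of larvae, so a spread between them may be technical.

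Per the submitters' processing notes, the reads were aligned with Bowtie 0.12.7. The program that called the regions, its thresholds and the way the replicates were combined are not given in the sources used here. The data were 3 deposited lists of regions of significant enrichment, of which 1 belonged to each ChIP sample and 1 to the whole series. Each input sample is described in the labels as the input of the ChIP sample with the same number, and no values of the input samples were analysed here. Coordinates are those of FlyBase release 5, per the file headers, counted from 1, and sequence lengths were taken from the same headers.

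Each region carries a score that the authors' processing assigned to it, and the scale of this deposited score is not stated. The scale was examined from the scores that occur at least 4 times in a list. With base 2, the difference of such a score from the most frequent one was the logarithm of a ratio of whole numbers up to 100, within a relative tolerance of 1e-07, for 32 of 39 scores in replicate 1, 39 of 62 in replicate 2 and 29 of 39 in the whole-series list. With natural logarithms or base 10 the count was 0 in each list. Scores were used to describe, rank and filter regions within a list. Across lists, scores of named regions are given side by side, values of the replicates are averaged, and paired regions are compared, on the assumption that the lists share a scale. The whole-series list also held 1 region of depletion, which was left out of all counts.

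The lists hold no read counts, so the depth of the libraries is unknown, as is the precision that depth gives to a boundary or a score. Intervals given for shares of regions are 95% Wilson intervals. They cover the counting of regions only, and neighbouring regions are not independent. With 2 replicates of 1 group, no test between groups of samples was possible, and values are given per replicate or as mean ± SD (n = 2).

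Regions of different lists were taken to meet when they shared at least 1 bp (bedtools 2.31.1). Chance overlap was obtained from 1000 circular rotations of one list along each sequence, and the one-sided p is the share of rotations with at least the observed overlap, the observed value included. X was compared with the arms 2L, 2R, 3L and 3R in blocks of 1 Mb, taking the covered percent and the median score of each block and permuting the X label over the blocks 100000 times in a two-sided test. A block shorter than 50% of that length at the end of an arm was left out. Benjamini-Hochberg adjustment covered the 4 tests of the 2 replicates. Numbers of heterochromatic regions were compared between replicates with a two-sided Fisher's exact test. Intervals in the closing section came from 2000 bootstrap samples of blocks or of regions, or from exact binomial limits. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

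Both tests were first tested on simulated data. In 100 simulated pairs of unrelated lists of 5630 regions, the rotation test called 2% at p under 0.05. The unrelated lists were rotated copies of replicate 1, so the 2% says little of lists that differ in other ways. In 100 pairs that shared 50% of their regions the rotation test called 100%. The shared regions were exact copies, so that 100% of them met holds by construction. In 100 simulated lists of 5604 regions with no difference of X, the block test called 6%. With a score shift of 0.1 on X it called 100%, and the mean recovered shift was 0.10. Scores were drawn independently for each region, with fewer permutations than in the analysis. Correlation of scores between neighbouring regions or blocks was therefore not covered by this simulation.

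The comparisons of the lists, the coverage of the arms, the rule for named regions and most alternatives were fixed before the data were examined. For chromosomes, the written plan held coverage and shares, without a test. It did not name the comparison of X scores, the block permutation test or Fisher's exact test. The windows of 1 Mb and those for chromosome 4 were not in it either. The regions named are the 5 best-scoring and the 5 widest regions of the whole-series list that meet a region of both replicates, and the widest such region of each chromosome arm and of chromosome 4. Other single regions and stretches given in the text were chosen after their values were seen. The alternatives were an overlap of at least 50%, a reciprocal overlap of at least 50%, the best-scoring 50% of regions, joining of regions within 1 kb, the arms and chromosome 4 alone, random placement in place of rotation, shares by number of regions, the whole-series list in place of the replicates, and each replicate left out in turn. Added after the data were seen were chance shifts of 20 to 500 kb, blocks of 2 Mb, regions shared by the replicates, arms without the 1 Mb at the centromere, and the coverage of arm ends with its alternatives.

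The planned analyses of genes (location in genes, covered genes, gene lists and position along genes) were not run. The gene table at hand follows Release 6 of the genome and the regions follow release 5, and positions of different releases were not mixed. No gene is named for this reason.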

Results

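H3K36me1, a methylation state of a histone residue whose methylation is in general linked to transcribed gene bodies, was measured by ChIP-seq in nuclei of wild-type Drosophila larvae of instar 3. Region lists of 2 ChIP replicates and 1 list of the whole series were analysed. The depth of the libraries is unknown, and the score of a region is the authors' own value, of unstated scale.

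H3K36me1 regions were numerous and mostly short, and a small class of broad domains held a large part of the covered length. Replicate 1 held 5645 regions over 27.7 Mb and replicate 2 held 5725 regions over 26.5 Mb, giving 5685 ± 56.6 regions and 27.1 ± 0.83 Mb (SD, n = 2). They covered 23% and 22% of the chromosome arms and chromosome 4. The median width was 2300 bp in replicate 1 and 2225 bp in replicate 2. Regions of at least 10 kb made up 11.6% of the regions of replicate 1 (654 regions) and held 47.4% of its covered length. In replicate 2 they made up 10.5% (603 regions) and held 44.1%. Wide regions also had higher scores. Spearman's rho of width and score was 0.83 in replicate 1 and 0.81 in replicate 2, across regions, which are not independent replicates. The best-scoring 50% of regions had a median width of 4538 bp, the mean of the replicates.

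The widest domain of the genome was on 3R at 6328808 to 6499246, which is 170.4 kb in the whole-series list. Replicate 1 covered 98.5% of it, with a widest region of 166.5 kb, and replicate 2 covered 97.6%, with a widest region of 162.8 kb. The domains next in width in the whole-series list were on 3L at 711974 to 826897 (114.9 kb) and on 2R at 8824199 to 8931082 (106.9 kb). They were followed by 3L at 17913396 to 18019473 (106.1 kb) and 2L at 12455314 to 12546383 (91.1 kb). The replicates covered 99.5% ± 0.10, 98.7% ± 1.25, 98.4% ± 1.25 and 99.5% ± 0.16 of these 4 domains (SD, n = 2). The boundaries inside a domain differed more than its extent. The 3L domain at 17913396 was split into 3 regions in replicate 1 and 6 in replicate 2, and the 2R domain into 2 and 4. The widest domain of X in the whole-series list, at 3237962 to 3310010, was 72.0 kb. It was split into 2 regions in replicate 1 and 3 in replicate 2, the widest of 44.2 and 44.1 kb. That of chromosome 4, at 529187 to 552563, was 23.4 kb and was covered to 93.9% ± 1.87 (SD, n = 2). It was split into 2 regions in each replicate, the widest of 19.0 and 18.7 kb.

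The best-scoring regions of the whole-series list that met both replicates lay on 4 arms. The first was on 2L at 1626854 to 1680057, a domain of 53.2 kb with a score of 2.03 in the whole-series list, 2.05 in replicate 1 and 2.01 in replicate 2. Next came 2 regions of X, at 15697931 to 15706614 (8.68 kb) and at 12606005 to 12629032 (23 kb). Their replicate scores were 2.03 ± 0.09 and 2.00 ± 0.12 (SD, n = 2). The region on 3R at 12067895 to 12086457 (18.6 kb) was 1 region in replicate 2, with a score of 1.93. In replicate 1 it was split into 2 regions, the widest of 10.3 kb, and the better of their scores was 2.28. These 2 scores are therefore not of like regions. The region on 3L at 543054 to 570899 (27.8 kb) reached 2.01 in replicate 1 and 1.82 in replicate 2. Which genes or exons lie in these regions was not analysed here, since no gene positions of release 5 were used.

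The replicates placed most H3K36me1 regions at the same positions, and every broad domain of one was met by the other. Of the regions of replicate 1, 4521 of 5645 met a region of replicate 2, which is 80.1% (Wilson 95% interval 79.0% to 81.1%). Of the regions of replicate 2, 4819 of 5725 met replicate 1, which is 84.2% (83.2% to 85.1%). Rotated lists met in 33.9% and 34.2% of regions on average, and in at most 43.3% and 41.2%. In base pairs, 23.8 Mb of a union of 30.5 Mb were shared. This is 78.0%, against 12.7% on average and 19.8% at most after rotation. Each p was 0.001, the smallest that 1000 rotations can give. Agreement rose with width. Regions of up to 2 kb met the other replicate in 58.0% of cases for replicate 1 and 67.0% for replicate 2, those of 2 to 5 kb in 92.1% and 94.2%, those of 5 to 10 kb in 99.7% and 100%, and all 654 and 603 regions above 10 kb did. A wider region meets another more easily by chance as well, and chance was not simulated by width class.

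**Figure D1:**
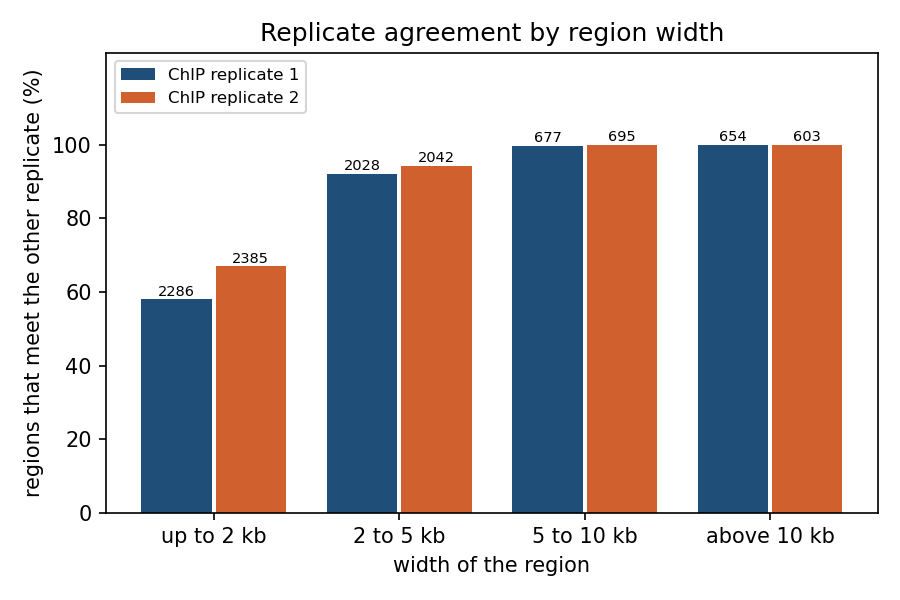
Percent of the regions of each ChIP replicate that meet a region of the other replicate by at least 1 bp, by width of the region, with the number of regions above each bar. Of the regions up to 2 kb, 58.0% of replicate 1 and 67.0% of replicate 2 met the other list, and all regions above 10 kb did.

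Regions found in a single replicate were short, and low in score as short regions were in general. The 1124 regions of replicate 1 that met none of replicate 2 had a median width of 1567 bp and a median score of 0.46, against 2899 bp and 0.61 for those that met one. In replicate 2 the 906 unmatched regions had a median width of 1559 bp and a median score of 0.52, against 2654 bp and 0.62. Score rises with width, and all regions of up to 2 kb had median scores of 0.44 in replicate 1 and 0.47 in replicate 2. The low score of unmatched regions is therefore not shown to be separate from their short width. For 3410 pairs of regions that met one to one, the scores of the replicates correlated with a Pearson r of 0.94 and a Spearman's rho of 0.87. The median absolute difference in width was 266.5 bp. These correlations are across regions and describe 1 pair of samples.

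The whole-series list was a separate and longer set of regions, and neither the union nor the intersection of the replicate lists. It held 8190 regions over 36.2 Mb. Of these, 3836 met both replicates (46.8%, Wilson 95% interval 45.8% to 47.9%). They had a median width of 4122.5 bp and held 29.0 Mb. A further 997 regions met replicate 1 alone, 776 met replicate 2 alone, and 2581 (31.5%, 30.5% to 32.5%) met neither. The last class was short, with a median width of 1296 bp, and held 3.64 Mb. It had a median score of 0.34, against 0.54 for regions that met both. The whole-series list contained 99.3% of the union of the replicates and was 1.19 times as long, with 5.96 Mb outside the union. Only 8 regions of replicate 1 and 15 of replicate 2 lay entirely outside it.

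H3K36me1 coverage was similar among the large arms and changed strongly along them. Regions covered 21.2% ± 0.57 of 2L, 23.2% ± 0.60 of 2R, 23.8% ± 0.59 of 3L and 23.1% ± 0.63 of 3R (SD, n = 2). In 119 windows of 1 Mb the median coverage was 23.2%, and the range went from 0 to 50.2%. The most covered windows were 3L 0 to 1 Mb (50.2% ± 1.60), 3R 5 to 6 Mb (41.8% ± 2.75), 2L 0 to 1 Mb (40.6% ± 2.32) and X 13 to 14 Mb (39.5% ± 2.61). The least covered windows lay at centromere ends. The last windows of 3L, 23 to 24 Mb and 24 to 24.54 Mb, were covered to 0.34% and 0%, and the first of 2R, 0 to 1 Mb, to 1.94%. The windows of the replicates differed by a median of 1.05 percentage points and by at most 4.76, far less than the SD of 9.06 points over windows. Spearman's rho between the replicates over windows was 0.98.

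**Figure D2:**
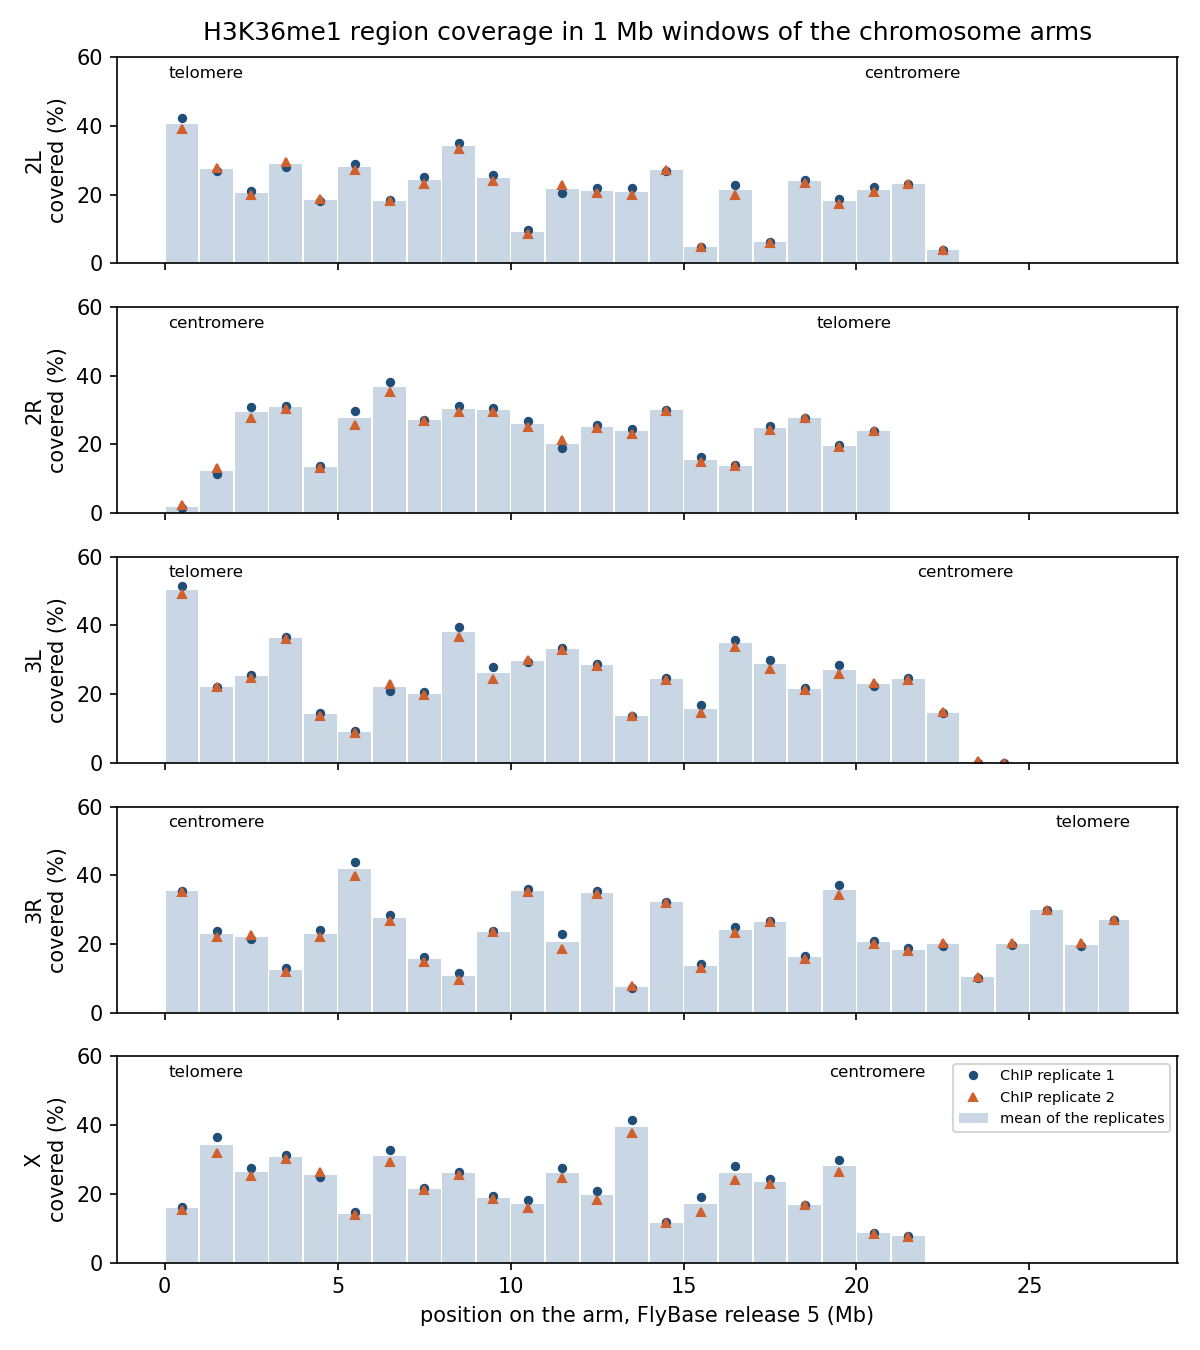
Percent of each 1 Mb window covered by H3K36me1 regions along the arms 2L, 2R, 3L, 3R and X (FlyBase release 5). Points give each ChIP replicate and bars their mean. The first window of 3L reaches 50.2%, and the windows at the centromere ends of 2L, 2R, 3L and X lie below 10%, while that of 3R is at 35.3%.

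The ends of the arms were unlike one another. Over the 1 Mb at the telomere, coverage was 50.2% on 3L, 40.6% on 2L, 24.4% on 3R, 21.2% on 2R and 15.8% on X. Over the 1 Mb at the centromere, coverage was 0% on 3L, 1.94% on 2R, 3.85% on 2L and 7.71% on X. Over 2 Mb at the centromere it was 4.72% on 3L, 7.11% on 2R, 13.1% on 2L and 6.70% on X, so their order depends on the window. The centromere end of 3R differed from the others with 35.3% ± 0.08 over 1 Mb (SD, n = 2), above the 23.1% of that arm as a whole. Over 2 Mb it was 29.1%. Windows start at the ends of the arm sequences, and how far each end lies from the centromere was not examined. The SD between replicates was at most 2.32 points at any of these ends.

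X carried H3K36me1 regions of higher score than the autosomal arms, and its coverage did not differ from theirs in a way that passed the test. The median score on X was 0.66 in replicate 1 and 0.67 in replicate 2. On the 4 autosomal arms together it was 0.55 and 0.57. Over blocks of 1 Mb, the median score was 0.11 higher on X in replicate 1 and 0.10 higher in replicate 2 (22 blocks of X and 96 autosomal blocks). In the permutation test p was 1e-05 in each replicate, the smallest that 100000 permutations can give, and 2e-05 after adjustment over 4 tests. If the score is on a base 2 logarithmic scale, these differences correspond to ratios of 1.08 and 1.07. The permutation test treats blocks as independent, though all blocks of X come from a single chromosome. Its p measures the spread among blocks and not among chromosomes, and the replicates share the same blocks. X was covered to 21.8% ± 1.28, and the autosomal arms to 22.8% ± 0.60 (SD, n = 2). Over blocks, the difference in coverage of X from the autosomal arms was -0.20 percentage points in replicate 1 (permutation p = 0.93) and -1.18 points in replicate 2 (permutation p = 0.57), neither of which passed the test. X had 46.6 ± 0.28 regions per Mb and the autosomal arms 47.4 ± 0.42. Among the best-scoring 50% of regions, a set chosen on the score itself, the score difference was -0.022 (permutation p = 0.22) and the coverage difference 1.65 points (permutation p = 0.4). The coverage difference was 0.28 points in the whole-series list (permutation p = 0.91).

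**Figure D3:**
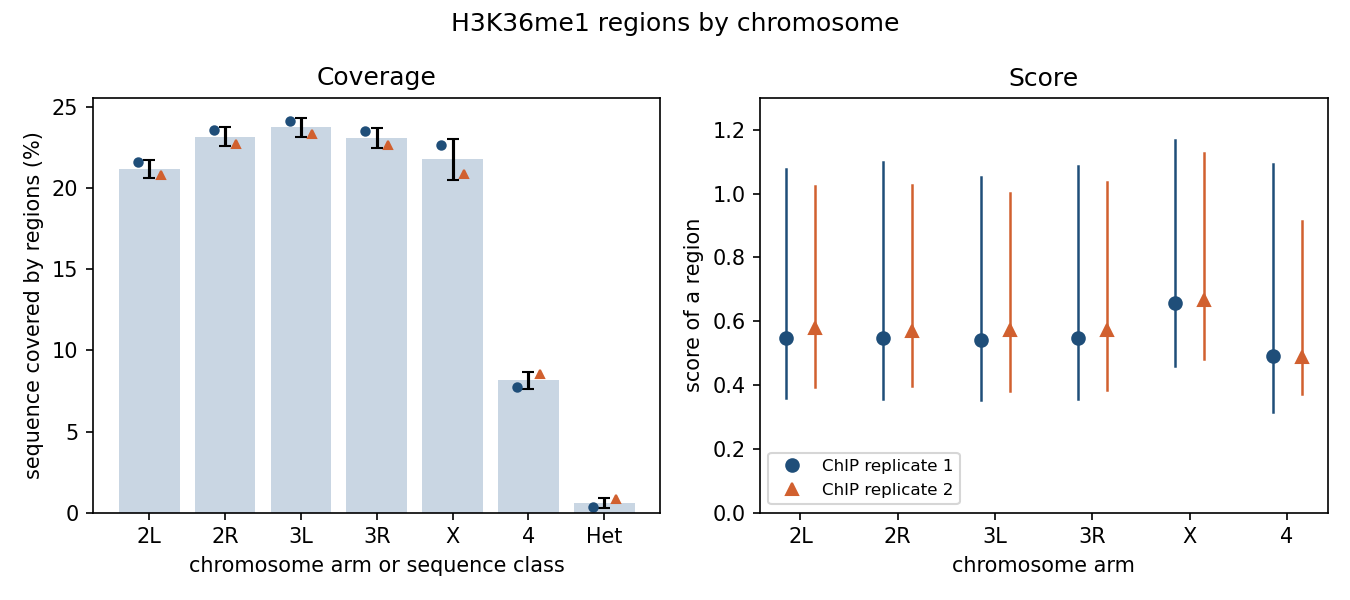
Left, percent of each chromosome arm, of chromosome 4 and of the heterochromatic sequences (Het) covered by H3K36me1 regions, with bars for the mean, error bars for the SD and points for the 2 ChIP replicates. Right, score of the regions of each arm, with points for the median and lines from the 10th to the 90th percentile of regions in each replicate, where X has the highest medians, 0.66 and 0.67.

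Chromosome 4, a small chromosome with many heterochromatic features, was covered less by H3K36me1 regions than each large arm as a whole. How much of it reads can be aligned to was not tested, so low coverage may not mean little of the mark. Regions covered 8.15% ± 0.53 of it (SD, n = 2), with 26 regions in replicate 1 and 35 in replicate 2, or 22.6 ± 4.71 regions per Mb. Of 86 windows of the same length on the arms, 3 were as low in replicate 1 and 5 in replicate 2, so this coverage is low and still within the range of the arms. The coverage was 13.2% in the whole-series list and 5.03% with the best-scoring 50% of regions, below the autosomal arms under the same settings (30.2% and 17.9%).

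The separately assembled heterochromatic sequences were almost without regions. They were covered to 0.37% in replicate 1 and 0.82% in replicate 2, with 14 and 36 regions over 9.28 Mb. How much of these sequences reads can be aligned to was not tested, so few regions may not mean little of the mark. In the whole-series list the coverage was 1.42%, and with the best-scoring 50% of regions it was 0.34%, the mean of the replicates. No region was called in either replicate on the heterochromatic Y sequence of 0.35 Mb or on the larger set of unplaced sequences. A count of 0 allows up to 8.64 and 0.10 regions per Mb there, if a region could be called at any base. Where reads cannot be aligned, the count sets no limit. The replicates differed here by more than their total numbers would give. With unplaced sequences included, 15 of 5645 regions of replicate 1 and 38 of 5725 regions of replicate 2 were heterochromatic or unplaced (two-sided Fisher's exact test, p = 0.0022). This test treats regions as independent and compares these samples only.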

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

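The chance shifts of 20 to 500 kb, the blocks of 2 Mb, the shared regions, the arms without the 1 Mb at the centromere and all values for arm ends were chosen after the data were seen. Of 81 alternative values for 17 results, 56 kept their direction and their side of the threshold, or, for values without a test, moved by less than the spread between replicates (for numbers of regions, by under 1.5 times). For 20 of these 56, values without a test and with 1 of 2 replicates left out, the move is below 1 SD by construction and says nothing of stability. The share of regions that met the other replicate ranged from 68.1% to 81.4% for replicate 1 and from 67.1% to 84.6% for replicate 2, and the shared length from 78.0% to 79.8%, each with a permutation p of 0.001, the smallest possible. The score difference of X from the autosomal arms was between 0.08 and 0.12 in 6 alternatives, each with the smallest possible permutation p, 1e-05. It reversed to -0.0216 (permutation p = 0.22) with the best-scoring 50% of regions. This selection kept 69.0% of the regions of X in each replicate, and 45.7% and 45.9% of those on the autosomal arms. It sets the same lowest score for all arms, and why the score difference was absent above it was not tested. The coverage difference of X, -0.69 points and not past the threshold, turned to 1.65 with the best-scoring 50%, through the same selection, and to 0.28 with the whole-series list, cause not tested (permutation p = 0.4 and 0.91).

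With the best-scoring 50% of regions, the number of regions was 2842, by construction, the median width 4538 bp, the covered length 21.8 Mb and the median score 0.77. Coverage was then 17.9% on the autosomal arms, 19.3% on X, 5.03% on chromosome 4, 25.2% at telomere ends and 7.85% at centromere ends. X held 19.9% of the covered length, and 48.1% of whole-series regions met both replicates. With the whole-series list, coverage was 30.2% on the autosomal arms, 30.0% on X, 13.2% on chromosome 4, 1.42% on the heterochromatic sequences, 38.6% at telomere ends and 12.8% at centromere ends, and X held 18.6% of the covered length. Joining regions within 1 kb gave 4297 regions with a median width of 2824 bp, an overlap of at least 50% left 42.5% of whole-series regions meeting both replicates, and ends of 2 Mb were covered to 28.0% and 12.1%. A subset, a joined or a longer list moves numbers and lengths by construction, and for the share of X in the whole-series list and the ends of 2 Mb the cause was not tested.

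With 1 replicate left out in turn, the number of regions was 5645 to 5725 and the median width 2225 to 2300 bp. Heterochromatic coverage was 0.37% without replicate 2 and 0.82% without replicate 1. No paired analysis was possible because no values of the input samples were analysed here. The alternatives for the 4 analyses of genes were not run. Depth, which is unknown, limits all values.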

Other observations

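The tests of wider regions and of a few strong regions on X, of the shorter minimum width of the whole-series list and of a more permissive list of replicate 2 were chosen only after the result was seen, as were the stretches and short regions described next. The test in regions no wider in the whole-series list was added once the score difference over all matched regions was known, with its prediction set before its own value was seen and the minimum of 20 regions set after.

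No H3K36me1 region was called over long stretches inside the arms in either replicate. The longest stretch between regions was on 2L at 17499173 to 18134872, 635.7 kb without a region in either replicate, and 2L held the 2 next longest as well, at 15765535 to 16249687 (484.2 kb) and at 22163137 to 22646232 (483.1 kb). The longest such stretch was 405.3 kb on 3L (4725970 to 5131306), 395.5 kb on X (14150571 to 14546038), 352.7 kb on 3R (2282385 to 2635075), 298.2 kb on 2R (711650 to 1009806) and 150.8 kb on chromosome 4 (187042 to 337814). The whole-series list placed 3 regions in the longest of them and 9 in that of 3L. At the centromere end of 3L, the last 1213 kb (23330720 to 24543557) held no replicate region and 2 regions of the whole-series list. Whether these stretches hold genes, or sequence to which reads cannot be aligned, was not tested.

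Very short regions with high scores stood apart from the broad domains in the whole-series list. The 6 best-scoring whole-series regions that met neither replicate were 1001 to 1029 bp wide. The first, on 2R at 311277 to 312305, had a score of 2.71, the highest of that list. Next were 2R at 5040714 and 2L at 12734819, both at 2.51, chromosome 4 at 615336 (2.05), an unplaced sequence at 9623011 (1.75) and chromosome 4 at 1317763 (1.75). All 6 were below the minimum width of 1301 bp found in each replicate list. The 1 region of depletion in the whole-series list was on 3R at 16410239 to 16411736, with a score of -0.03.

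The higher score of X regions was tested against 3 technical explanations. If a higher calling threshold on X had removed weak regions, regions with a score of at least 1 would be as dense on X as on the autosomal arms, yet their density was 1.41 times as high (1.39, 95% interval 1.09 to 1.70, in replicate 1 and 1.43, 1.12 to 1.78, in replicate 2). Within classes of width the score difference over all regions was still 0.10, which argues against wider regions as the cause, and at the 10th percentile it was 0.10, which argues against a few strong regions. A single factor on all values of X, such as one from normalization or from X copy number in larvae of unstated sex, could give a shift of this kind, as could noisier scores from fewer reads on X, and neither was tested. No biological explanation was tested, since the design holds 1 genotype and 1 stage.

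The whole-series list was 1.19 times as long as the union of the replicates. Regions shorter than 1301 bp, the minimum width of the replicate lists, held 25% of the length outside the union, so the shorter minimum of 1001 bp accounts for part of it at most. A lower threshold stays open. In 2838 regions matched one to one in all lists the whole-series score differed from the mean of the replicates by a median of -0.0635 (95% interval -0.0655 to -0.0613), but 2834 of them were wider in the whole-series list, which could dilute a score over the region, and the 4 that were not (median difference -0.00968) are too few to decide. Calling on combined reads was not tested, nor was any biological explanation.

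Replicate 2 had 2.53 times as many heterochromatic or unplaced regions as replicate 1 (exact 95% interval 1.36 to 4.96). A list that is more permissive everywhere would show the same ratio on the arms and chromosome 4, where it was 1.01. The excess lay mostly on the heterochromatic sequences of 2R (6 regions in replicate 1 and 18 in replicate 2) and 3L (2 and 11). Those of 3R held 4 and 5 regions, those of 2L 0 and 1, those of X 2 and 1, and unplaced sequences 1 and 2. Regions near the threshold in replicate 1 remain a possible explanation that cannot be told apart from others with these lists. Of 29 heterochromatic or unplaced regions found in replicate 2 alone, 27 (93.1%) were in the whole-series list, but so were 98.5% of the replicate 2 regions of the arms that replicate 1 lacked, so this share is near its ceiling for any region. No biological explanation was tested.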
